A study of Mus musculus with 4 samples.

How the data were processed

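RNA abundance was measured in scraped ileal mucosa of male Cyp27a1(-/-) mice with 4 single-colour Affymetrix arrays, 2 from animals given GW4064 and 2 from animals given vehicle. Groups, replicate numbers, dose and times were taken from the sample labels. Per the labels' protocols, total RNA was extracted with RNA STAT-60 and labelled with biotin. The deposited values are one linear intensity per probe set and array. The software that summarised the probes, its version, any detection calls and the genome build of the probe annotation are not given in the sources used here. The values themselves show how they were scaled, since after trimming 2% of probe sets at each end the mean intensity was 200.1 on every array. The highest of these trimmed means was 1.00 times the lowest, so the deposited intensities were used without further normalisation, by a rule set before the data were examined.

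The table held 22690 probe sets, of which 64 were array controls and were left out. Probe sets were named through the platform annotation, and symbols were checked against a RefSeq gene table (assembly GRCm38.p6) through the Entrez identifier, which changed 0 symbols. Among the remaining probe sets 20380 named 1 gene, 691 named several and 1555 were unnamed here. Only those naming 1 gene were used for genes. No coordinates are printed, because no build was stated for the annotation. The reference table served only for names and for the order of neighbouring genes.

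Intensities were taken as log2(intensity + 32). A fold change on this scale understates the change of dim genes. Probe sets in the lowest 40% by mean log2 value over the 4 arrays were left out, a level equal to an intensity of 30.9, which left 13575 probe sets. Each gene was represented by its brightest remaining probe set, giving 7971 genes. The comparison of GW4064 with vehicle was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance), with 2 residual degrees of freedom per gene, two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method at a threshold of 0.05. Errors given with intensities are SDs of 2 arrays, and errors given with log2 fold changes are limma's moderated standard errors. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333, so none was used.

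Before the data were examined, 42 gene lists of pathways and cell types were fixed, and 38 had the 3 or more measured genes needed for a test. Lists were tested with camera at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry, and adjusted over the 38 lists. Camera compares a list with all other genes, whereas fry asks whether its genes move on balance one way (or, in its mixed form, either way) without that comparison. No list passed with an estimated correlation, where the smallest adjusted p was 0.510, so a call lost there is not particular to any list. That form of camera takes its p from the 2 residual degrees of freedom, so a pass over 38 lists is hardly within its reach. The estimated correlation was -0.14 for the FXR target list, -0.30 for the antibacterial list and 0.04 for the interferon-stimulated list. For the first 2 of these, correlation between genes therefore did not cost the call. Members of a list were also adjusted over the list alone. The genes named were fixed by rule: Cyp27a1 and Nr1h4; all measured members of the FXR target and antibacterial lists; the 12 largest rises and falls among genes passing the threshold, filled up to 12 per direction with the smallest unadjusted p among genes with a log2 fold change of at least 1 in size; and up to 4 members with the smallest unadjusted p of each list described. Genes named outside this rule are said to be so.

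The fit was tested on simulated data with the means and spread of this comparison, in 20 simulations of 7981 genes with 200 genes changed. It recovered 63.2% of genes changed by 1 on the log2 scale, 95.4% of those changed by 2 and 98.8% of those changed by 3. Of its calls 5.32% were false, and with no gene changed it made 0.15 calls on average. Shifted lists were found in 100% of cases and unshifted lists in 2.50% at an unadjusted p under 0.05. Errors were drawn independently for each probe set and array, without correlation between genes or differences between replicate numbers. These rates belong to that setting and need not hold for the arrays themselves.

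Alternatives were fixed beforehand for the pseudocount (1 and 128), the filter (none, and the lowest 60%), the normalisation (quantile, median centring, cyclic loess), the prior of limma's test (no trend, robust), the summary per gene (mean of its probe sets, or all probe sets tested singly), the replicate number as a block, each array left out in turn, the list test and the threshold. The number of arrays limits the precision of every value. The labels name the arrays of a group as replicates without saying that they came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.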

Results

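The series measured which transcripts of the ileal mucosa respond to GW4064, a synthetic agonist of the farnesoid X receptor (FXR, encoded by Nr1h4), the nuclear receptor for bile acids. All animals were male mice of a mixed C57BL/6:129Sv background that lacked Cyp27a1, a mitochondrial sterol 27-hydroxylase of bile acid synthesis, and were 3 to 4 months old. They received GW4064 at 100 mg/kg or vehicle by gavage in 2 doses 12 h apart and were killed 14 h after the first. Each group had 2 arrays. The median intensity of an array lay between 54.2 and 56.8, and between 59.6% and 60.8% of its probe sets exceeded the level used as a filter. The 3′ to 5′ signal ratio of the Gapdh control probe sets was 0.795 and 0.799 in the GW4064 arrays and 0.835 and 0.802 in the vehicle arrays.

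Cyp27a1 read 107 and 120 on the GW4064 arrays and 106 and 132 on the vehicle arrays, a log2 fold change of -0.05 ± 0.14 (SE, n = 2 per group, limma adjusted p = 0.985). Because all 4 arrays came from knockout animals, and the place of the probe set relative to the deleted part is not given in the sources used here, this level does not check the genotype.

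GW4064 raised Fgf15, the intestinal hormone that represses bile acid synthesis in the liver, from an intensity of 26.7 ± 21.4 to 1270 ± 165 (SD, n = 2 arrays each). Its log2 fold change was 4.51 ± 0.25 (limma adjusted p = 0.020), the largest of all 7971 genes tested on the log2(intensity + 32) scale. Rnase4, a secreted ribonuclease, rose from 868 ± 55.8 to 2654 ± 322, a log2 fold change of 1.57 ± 0.11 (adjusted p = 0.039). These were the only genes past the threshold over all genes, 2 higher and 0 lower. At an adjusted p under 0.10 there were 9 higher and 1 lower. At an unadjusted p under 0.05, limma gave 287 genes higher and 261 lower, 548 in all, where 398.6 would be reached by chance. In 2806 genes (35.2%) both GW4064 arrays lay on one side of both vehicle arrays, against 33.3% by chance. Quantile normalisation called 8 genes higher and 1 lower, and median centring and limma's robust prior each 7 higher and 1 lower, whereas a pseudocount of 1, no filter or no trend in the prior called 0. The replicate number taken as a block called more genes in both directions than any other alternative, as described below. Without GW4064 replicate 1 only Nr0b2 passed, without GW4064 replicate 2 there were 4 higher and 1 lower, and without either vehicle array only Fgf15 passed.

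**Figure D1:**
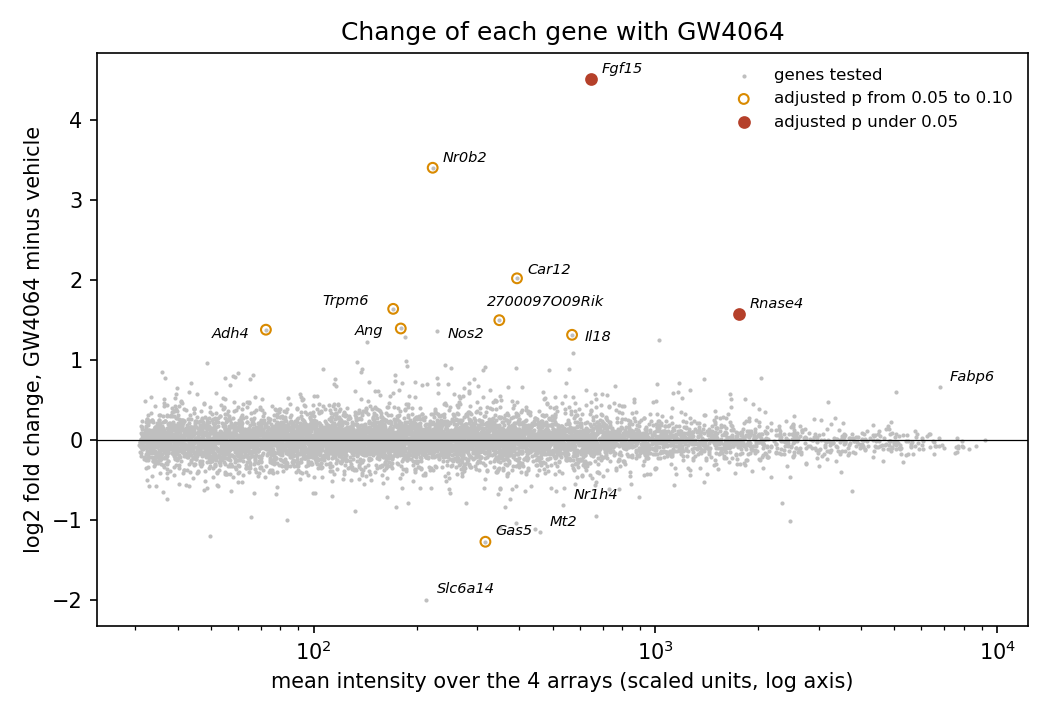
Log2 fold change of each of the 7971 genes (GW4064 minus vehicle, 2 arrays each) against its mean intensity over the 4 arrays on a log axis. Filled red points are the 2 genes with an adjusted p under 0.05, Fgf15 at 4.51 and Rnase4 at 1.57, and open orange circles are genes with an adjusted p between 0.05 and 0.10.

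The known FXR target genes were the direct readout of the agonist. Of the 8 measured, 3 rose when adjusted over the list alone and 5 did not pass, and over all genes 1 passed. Beside Fgf15, the nuclear receptor Nr0b2 (small heterodimer partner, a transcriptional repressor) rose from 9.61 ± 5.66 to 436 ± 232, a log2 fold change of 3.40 ± 0.34 (adjusted p = 0.00026 over the list alone, 0.064 over all genes). The vehicle means of Fgf15 and Nr0b2 lay below the filter level of 30.9, so their folds depend on the pseudocount, and with the other pseudocounts tried the log2 fold change was 3.18 and 5.77 for Fgf15 and 1.97 and 5.37 for Nr0b2. Fabp6, the ileal bile acid binding protein, rose from an already high 5240 ± 218 to 8313 ± 670, or 1.58-fold, a log2 fold change of 0.66 ± 0.09 (adjusted p = 0.00077 over the list alone, 0.154 over all genes). Insig2, a regulator of sterol synthesis, had a log2 fold change of 0.58 ± 0.20 and the proteoglycan gene Sdc1 0.23 ± 0.09, neither passing, and these were 0.31 and 0.15 without GW4064 replicate 2. Their other probe sets past the filter gave 0.37 and 0.30 for Insig2 and 0.07, 0.16 and -0.10 for Sdc1. The bile acid exporter subunit Slc51a, already at 4728 in vehicle, gave 0.08 ± 0.12, the conjugate pump Abcc2 0.00 ± 0.37 and the phospholipid transfer protein gene Pltp -0.07 ± 0.23, and with 1 array left out each of these took either sign. The bile salt and phospholipid pumps Abcb11 and Abcb4 were below the filter on these arrays, with mean intensities of at most 4.24 and 25.8. Slc51b was not analysed here. The list as a whole shifted up against all other genes, with a median log2 fold change of 0.40 and a mean of 1.17 (camera adjusted p = 1.0e-06, but adjusted p = 0.510 with an estimated correlation and fry adjusted p = 0.185). The median was 0.15 without Fgf15 and Nr0b2, an alternative chosen after seeing the data (camera adjusted p = 0.034), 0.15 with no filter and 0.25 with probe sets averaged.

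**Figure D2:**
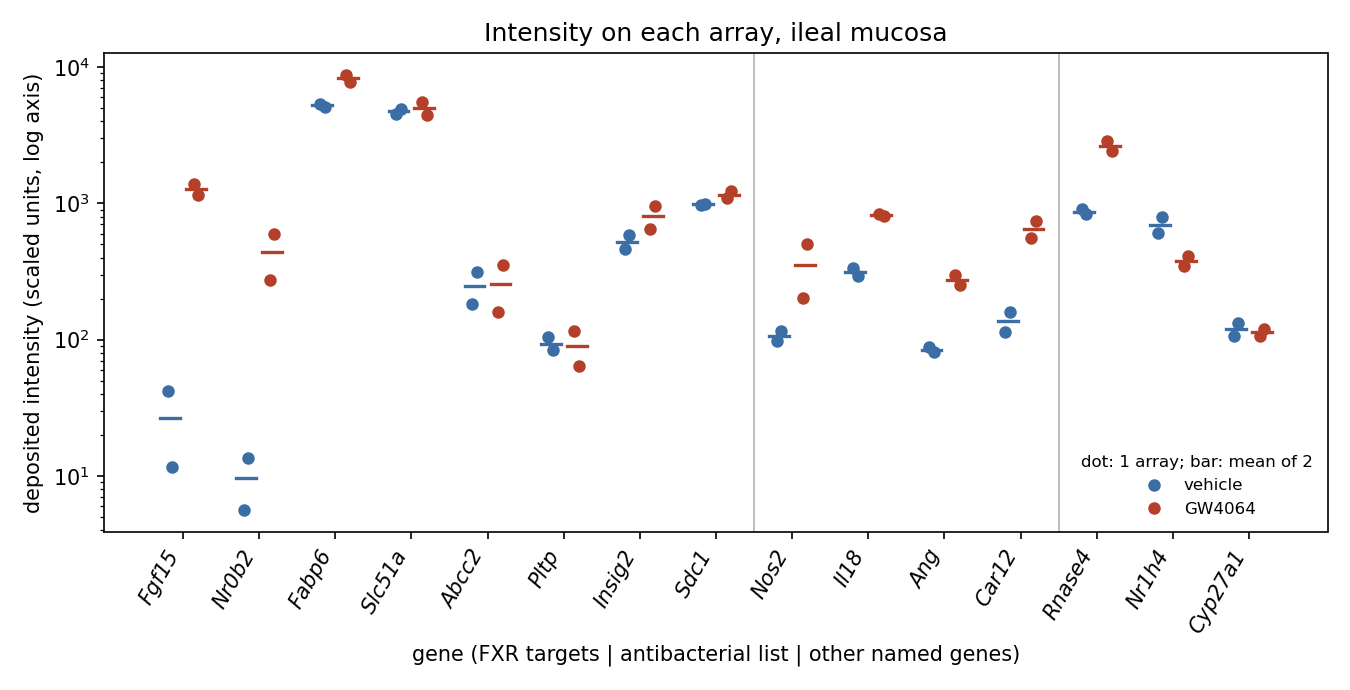
Deposited intensity (scaled units, log axis) of the measured FXR targets, the antibacterial list, Rnase4, Nr1h4 and Cyp27a1 on each array. Dots are single arrays and bars the mean of 2. Fgf15 reads 1386 and 1154 on the GW4064 arrays against 41.8 and 11.6 on the vehicle arrays.

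All 4 genes of a short antibacterial list were higher with GW4064. The list was named by the study itself and is therefore not independent evidence of the direction or of a change. The p-values over the list alone and of the list tests take no account of that choice. Car12, a membrane carbonic anhydrase, rose from 136 ± 32.8 to 651 ± 134, a log2 fold change of 2.02 ± 0.19. Ang, an angiogenin ribonuclease, rose from 84.6 ± 4.29 to 275 ± 35.7 (1.39 ± 0.13). Il18, the gene of the cytokine interleukin 18, rose from 314 ± 32.3 to 826 ± 21.9 (1.31 ± 0.11). Nos2, the inducible nitric oxide synthase, rose from 107 ± 12.5 to 354 ± 217 (1.36 ± 0.37), with GW4064 arrays at 201 and 507. All 4 passed when adjusted over the list alone (adjusted p = 6.5e-05 for Il18, Ang and Car12 and 0.011 for Nos2), and 0 passed over all genes, where the adjusted p was 0.056, 0.056, 0.054 and 0.554 for Car12, Ang, Il18 and Nos2. The median log2 fold change of the list was 1.37 (camera adjusted p = 2.1e-10, fry adjusted p = 0.033, and adjusted p = 0.510 with an estimated correlation). Without GW4064 replicate 2 the log2 fold change of Nos2 was 0.75.

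Of the 12 genes named for an increase, 2 passed over all genes, and the other 10 were those with the smallest unadjusted p among the genes with a log2 fold change of at least 1. Of those not yet described, Trpm6, an epithelial magnesium channel, read 275 ± 35.6 with GW4064 and 66.8 ± 14.1 with vehicle, a log2 fold change of 1.64 ± 0.16 (adjusted p = 0.056). Adh4, an alcohol dehydrogenase active on retinol, read 119 ± 5.39 against 26.3 ± 7.77 (1.38 ± 0.15, adjusted p = 0.094). Its vehicle mean too lay below the filter level, and its log2 fold change was 2.17 with the smaller pseudocount tried and 0.68 with the larger. The ubiquitin-like modifier gene Ubd (1.22 ± 0.26, adjusted p = 0.384), the glutathione transferase gene Gsta4 (1.09 ± 0.21, adjusted p = 0.290) and 1 predicted transcript (2.82-fold, adjusted p = 0.074) completed the set. On the chromosome Ang and Rnase4 are direct neighbours. Of the 19 other measured genes among the 10 nearest on each side of Ang, 0 passed and their median log2 fold change was 0.00.

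No gene was lower past the threshold over all genes. The non-coding transcript Gas5, host of small nucleolar RNAs, came nearest at 172 ± 5.55 with GW4064 and 464 ± 57.4 with vehicle, a log2 fold change of -1.28 ± 0.12 (adjusted p = 0.056), although its other probe sets past the filter gave -0.85 and -0.25. Slc6a14, a broad amino acid transporter, read 63.7 ± 26.5 against 363 ± 174 (-2.00 ± 0.34, adjusted p = 0.234). The metal-binding metallothionein gene Mt2 read 269 ± 8.23 against 647 ± 167 (-1.15 ± 0.17, adjusted p = 0.197). The remaining genes named for their decrease did not pass either. Cyp2c55 was at -1.01 ± 0.23, the cytokine signalling suppressor Socs3 at -1.04 ± 0.45 and ccdc198 at -1.21 ± 0.38 (-0.52 with the larger pseudocount, its GW4064 mean of 17.1 lying below the filter level). The interferon-inducible Ifi202b read 47.1 ± 34.8 with GW4064 and 120 ± 27.8 with vehicle. The arrays of the groups overlapped for Socs3, the uncharacterised 1810065E05Rik (-1.10 ± 0.55) and Rpgrip1 (-1.11 ± 1.20). Arrays of the same replicate number were compared after the data were seen, although the labels name no pairing. Socs3 was lower with GW4064 in number 1 (149 against 331) and in number 2 (337 against 746). So was 1810065E05Rik (105 against 278, and 325 against 695). Rpgrip1 was not lower in number 1 (784 against 712) but was in number 2 (24.3 against 256). With 1 array left out Socs3 lay between -1.59 and -0.49, 1810065E05Rik between -1.79 and -0.41, Ifi202b between -1.47 and -0.54, ccdc198 between -1.66 and -0.81 (below the filter without vehicle replicate 1), Cyp2c55 between -1.38 and -0.65, and Rpgrip1 between -3.04 and, without GW4064 replicate 2, a positive 0.82.

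Several nuclear receptors changed with the agonist. Of 13 measured, 1 rose and 3 fell when adjusted over the list alone, and 0 passed over all genes. The one that rose was Nr0b2. Nr1h4, the receptor for GW4064 itself, fell from 696 ± 132 to 379 ± 48.6, a log2 fold change of -0.82 ± 0.16 (adjusted p = 0.0094 over the list alone, 0.290 over all genes). Pparg, a regulator of lipid storage and epithelial differentiation, fell from 97.2 ± 2.88 to 34.1 ± 7.61 (-0.97 ± 0.15, adjusted p = 0.0041 over the list alone). Its log2 fold change was -1.50 with the smaller pseudocount tried and -0.47 with the larger. Vdr, the vitamin D receptor, fell from 789 ± 37.0 to 582 ± 7.65 (-0.42 ± 0.09, adjusted p = 0.013 over the list alone). With members moving both ways the list median was -0.06 while its mean was 0.08, and camera did not call it (adjusted p = 0.311), whereas fry's test for change in either direction did (adjusted p = 0.043).

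Interferon-stimulated genes had a median log2 fold change of 0.40, a shift up against all other genes with the preset correlation (camera adjusted p = 4.7e-07) that did not pass otherwise (adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.386). Of 13 measured, 5 rose when adjusted over the list alone, 0 fell and 8 did not pass, and 11 of the 13 had a positive fold change. Ifit1, an antiviral RNA-binding protein, rose from 209 to 424 (log2 fold change 0.91 ± 0.15), Ifit3 from 34.1 to 82.5 (0.80 ± 0.17), Rtp4 from 180 to 283 (0.58 ± 0.15) and the transcription factor Irf7 from 399 to 561 (0.46 ± 0.11). The other was Oas1a (0.32 ± 0.10), named after its values were seen. Ifit3 gave 1.28 with the smaller pseudocount tried and 0.38 with the larger. Over all genes 0 passed. Without vehicle replicate 1 the median of the list was 0.25. Lists of other defence programmes did not pass. The medians were -0.20 for 6 NF-kB and inflammatory genes (camera adjusted p = 0.311), -0.08 for 5 Reg family antimicrobial genes (0.443) and 0.01 for 6 genes of MHC class II presentation (0.708), with 0 members passing over any of these lists alone.

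In transport and metabolism single genes passed when adjusted over their list alone, and camera called none of these lists with all arrays. That adjustment takes no account of the number of lists, and no member of these lists passed over all genes. Among 12 genes of ion transport, Car12 and the chloride-bicarbonate exchanger Slc26a3 (759 to 1261, log2 fold change 0.70 ± 0.12) rose when adjusted over the list alone, and 10 did not pass (list median 0.12, camera adjusted p = 0.259). Among 7 genes of bile acid and organic anion transport only Fabp6 rose past the threshold over the list alone, while the organic anion transporter Slco3a1 gave 0.36 ± 0.14, the ileal bile acid uptake transporter Slc10a2 -0.31 ± 0.17 and the efflux pump Abcc3 -0.60 ± 0.26, none passing (median 0.00, adjusted p = 0.668). With 1 array left out Slc10a2 and Abcc3 lay between -0.56 and -0.07 and between -0.93 and -0.27. Abca1, a cholesterol exporter controlled by the liver X receptors, fell from 129 to 69.7 (-0.66 ± 0.13, adjusted p = 0.023 over the list alone), the only one of 10 genes of sterol transport (median -0.02, camera adjusted p = 0.488). The pantetheinase Vnn1 rose from 1024 to 1749 (0.76 ± 0.12, adjusted p = 0.010 over the list alone), the only one of 15 genes of fatty acid oxidation and PPAR alpha targets (median 0.04, camera adjusted p = 0.443). Of 18 genes of xenobiotic metabolism, Gstm3 rose (0.59 ± 0.14) and Cyp2c55 fell (-0.65 without GW4064 replicate 1) when adjusted over the list alone (median -0.15, camera adjusted p = 0.259). Without GW4064 replicate 1 or without vehicle replicate 2 camera called that list (medians -0.20 and -0.15). The stress gene Osgin1 rose when adjusted over the list alone (0.53 ± 0.13, adjusted p = 0.048) among 8 NRF2 targets (median -0.09, mean 0.01, camera adjusted p = 0.898). Of 13 heat shock and immediate early genes, Hspa1b rose (0.97 ± 0.24, or 0.61 without GW4064 replicate 2) and Junb fell (-0.38 ± 0.09), both when adjusted over the list alone (median 0.05, camera adjusted p = 0.691). Fry's test for change in either direction passed for ion transport (adjusted p = 0.013) and sterol transport (adjusted p = 0.021), beside the FXR, antibacterial and nuclear receptor lists. These passes are not all separate results. Car12 is in both the ion transport and the antibacterial list, and Nr0b2 in both the nuclear receptor and the FXR list.

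The remaining lists of metabolism and cell function with 3 or more measured genes gave no member past the threshold over its list alone. For 17 genes of cholesterol synthesis and uptake the median was 0.08, with 14 positive (camera adjusted p = 0.259), and Idi1 and Stard4 stood at 0.30 ± 0.09 and -0.25 ± 0.09. Without GW4064 replicate 2 or without vehicle replicate 2 camera called this list (medians 0.17 and 0.13). Fatty acid synthesis (10 genes, median 0.21, camera adjusted p = 0.546) included Fasn at 0.34 ± 0.12 and Elovl6 at 0.34 ± 0.10, and in the other direction Fads2 at -0.33 ± 0.11 and Elovl5 at -0.23 ± 0.09. The medians were 0.00 for lipoprotein assembly and lipid absorption (14 genes, 0.912), -0.07 for sugar transport and gluconeogenesis (9 genes, 0.627), -0.11 for amino acid and peptide transport (9 genes, 0.348), 0.00 for endoplasmic reticulum stress (16 genes, 0.708), -0.10 for epithelial barrier and junctions (11 genes, 0.259) and 0.07 for the circadian clock (14 genes, 0.668), with the camera adjusted p in brackets. Without GW4064 replicate 1 camera called amino acid and peptide transport (median -0.12). The aryl hydrocarbon receptor list had 2 measured members, too few for a list test, and one of them, Tiparp, rose when adjusted over the list alone (0.41 ± 0.10), named after its values were seen.

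**Figure D3:**
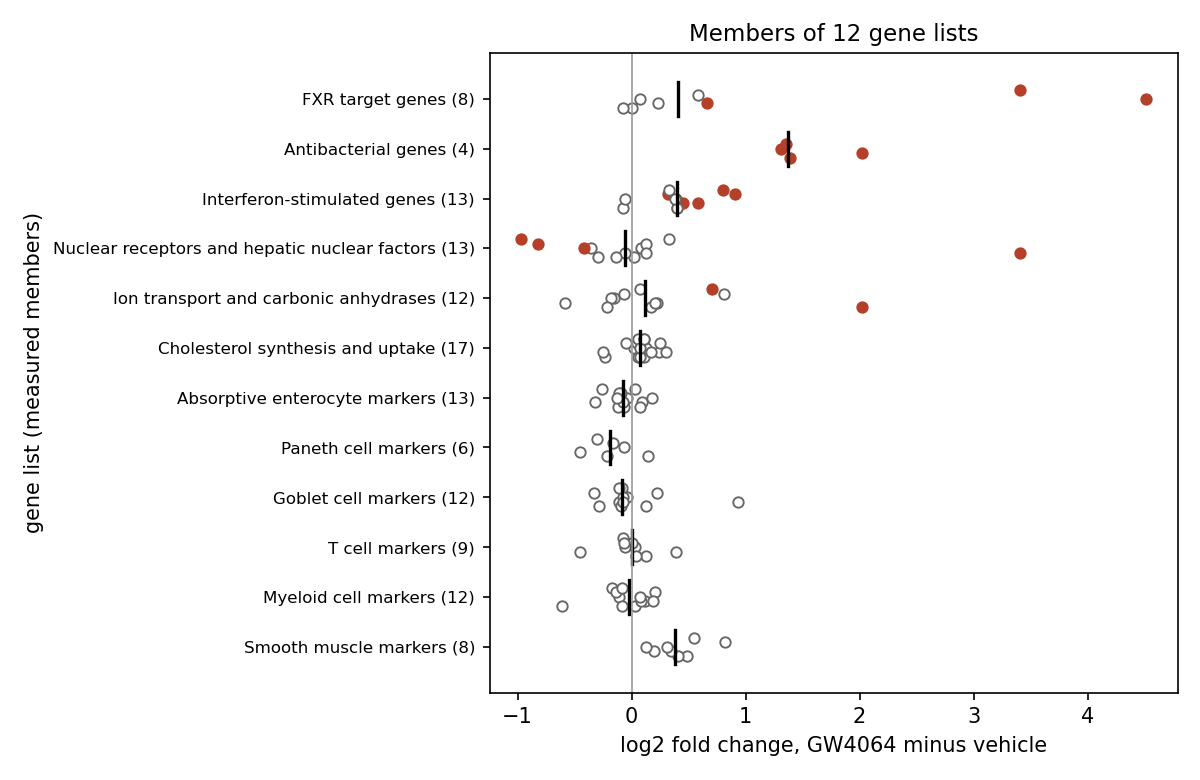
Log2 fold change (GW4064 minus vehicle) of every measured member of 12 of the lists. Each circle is a gene, filled where it passes adjusted over its list alone, and the vertical line is the list median. The medians are 0.40 for FXR targets, 1.37 for the antibacterial list and 0.40 for interferon-stimulated genes.

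Marker lists of cell types gave no shift past the threshold with all arrays. The epithelial lists had medians of -0.07 for absorptive enterocytes (13 genes, camera adjusted p = 0.450), -0.19 for Paneth cells (6 genes, 0.311), -0.08 for goblet cells (12 genes, 0.259), -0.07 for enteroendocrine cells (11 genes, 0.403), 0.13 for tuft cells (3 genes, 0.703), -0.04 for crypt stem cells (10 genes, 0.898) and 0.00 for proliferation (18 genes, 0.898). Regional markers of the proximal small intestine (7 genes, median 0.02, 0.905) and of the distal ileum and colon (6 genes, median -0.13, 0.450) did not pass either, and in the latter Fabp6 was the only member that rose when adjusted over the list alone. Immune lists had medians of 0.00 for T cells (9 genes, 0.979), -0.26 for B and plasma cells (8 genes, all negative, 0.117) and -0.02 for myeloid cells (12 genes, 0.892). Fibroblast (9 genes, median 0.17, 0.259), endothelial (5 genes, 0.17, 0.259) and exocrine pancreas markers (3 genes, 0.33, 0.311) did not pass. The 8 smooth muscle markers were all positive, with a median of 0.38 (0.451), and their levels differed far more within each group than between the groups. Acta2, a smooth muscle actin, read 473 and 1717 on the GW4064 arrays and 248 and 1584 on the vehicle arrays. Mast cell and adipocyte lists had 1 and 2 measured members and the erythrocyte list 0, too few for a test. Several of these results depended on a single array. Leaving out 1 array also makes the groups unequal in replicate number. The arrays numbered 2 differed from those numbered 1 in smooth muscle (median log2 difference 2.45), B and plasma cell (-0.52), myeloid (-0.48) and endothelial markers (-0.35). An effect of the agonist and a difference between the numbers cannot be told apart in such fits. The other lists named next did not differ between the numbers past the threshold. Their medians there were 0.03 for proliferation, -0.06 for goblet, -0.12 for fibroblast, -0.28 for exocrine pancreas, -0.18 for tuft and -0.16 for enteroendocrine cells. Without GW4064 replicate 1 camera called smooth muscle (median 1.54), B and plasma cells (-0.44), myeloid cells (-0.21), goblet cells (-0.19) and proliferation (0.19). Without GW4064 replicate 2 it called fibroblast (0.63), endothelial (0.60), exocrine pancreas (0.71) and tuft cell markers (0.58) and proliferation (-0.16). Without vehicle replicate 2 it called smooth muscle (1.63), B and plasma cells (-0.66) and enteroendocrine cells (-0.22).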

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

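The alternative without Fgf15 and Nr0b2 was chosen after the data were seen. The count of 2 genes higher became 0 with a pseudocount of 1, no filter or no trend in the prior, 1 with probe sets averaged or tested singly, 8 with quantile normalisation, 7 with median centring or a robust prior, 9 at an adjusted p under 0.10, and 1 to 4 with an array left out, where the lone array is assumed to vary like the others. The count of 0 lower became 1 with quantile normalisation, median centring, the robust prior and an adjusted p under 0.10, and 0 to 1 with an array left out. The cause was not tested. The FXR shift (median 0.40) was no longer called by camera with an estimated correlation (0.40, adjusted p = 0.510), where no list passed. Nor was it called by fry (0.40, adjusted p = 0.185). With an array left out this median was 0.27 to 0.54. Of the other lists 2 were called, against 0 with an estimated correlation, 1 with fry and 2 to 9 with an array left out. The proliferation median ran from -0.16 without GW4064 replicate 2, called and reversed, to 0.19 without GW4064 replicate 1. No scaling moved the median of all genes by more than 0.01.

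With the replicate number as a block, 31 genes were higher, 15 lower and 4 other lists called. Deviations of same-numbered arrays correlated at r = 0.450 over genes, but 2 pairs do not establish a pairing and the labels name none.

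For the 160 named genes, 2251 of 2361 values under an alternative kept direction and side of the threshold, 44 newly passed, 11 no longer passed and 55 changed direction without a call either way. For single lists 559 of 626 kept the direction and side of the list test. Signal over background is unknown without detection calls.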

Other observations

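The comparison of replicate numbers and the tests of explanations in this part were chosen after the results were seen, unlike the tests of the interferon-stimulated list itself.

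Some genes differed with the replicate number of the array in both groups alike. With treatment in the model, limma found 66 genes that differed between the arrays numbered 2 and those numbered 1, 44 higher and 22 lower in number 2 (adjusted p under 0.05), and these genes were named after their values were seen. The higher ones included Gdpd3, with the largest log2 difference of 3.92 ± 0.25, the smooth muscle genes Actg2 (3.04 ± 0.12), Cnn1 (2.60 ± 0.13) and Tagln (2.47 ± 0.10), and the acute phase genes Saa1 (2.10 ± 0.15) and Saa2 (1.12 ± 0.14). The alpha-defensin gene Defa31 read 8863 and 8668 on the arrays numbered 1 and 3.46 and 1.40 on those numbered 2. The immunoglobulin genes Igk (-1.25 ± 0.13) and Ighm (-0.70 ± 0.10) were lower in number 2, as were the lists of B and plasma cells (median -0.52, camera adjusted p = 4.8e-05) and myeloid cells (median -0.48, camera adjusted p = 1.4e-07). Camera also called the lists of lipoprotein assembly (median -0.15, adjusted p = 0.0032), endothelial cells (-0.35, adjusted p = 0.048) and bile acid transport (0.31, adjusted p = 0.043). These list calls between the numbers rest on the preset correlation alone, since neither an estimated correlation nor fry was tried for them.

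The scrapings numbered 2 may have held more of the muscle layer. All 8 measured smooth muscle markers were higher there past the threshold, with a median of 2.45. Dilution of the mucosa by muscle would lower all mucosal genes by one factor, but the medians of the absorptive enterocyte, goblet and Paneth cell lists were -0.06, -0.06 and 0.21 and their lower quartiles -0.13, -0.12 and 0.01. Of the 22 genes lower in number 2 (median -0.78), 20 lay below the enterocyte median when tested against it by limma over all genes, by falls of 0.62 or more. The other 2, Creb3l3 and Treh (median -0.55), had adjusted p = 0.055 in that test. The 22 were selected for their falls on the same arrays. That test was therefore nearly fixed in advance and cannot decide on dilution. The epithelial lists were not so selected, and their values argue against a dilution of the epithelium as large as these falls. They do not cover genes of other mucosal cells, and a smaller contribution stays open for all 22. Alleles of the parental strains shared by animals of one number stay open for a gene such as Defa31 (log2 difference -8.00), because the labels give no genotype per array. The labels do not say what the numbers share, so the design gives no group to set against these explanations.

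Ang and Rnase4, neighbours on the chromosome, were both higher with GW4064. A hypothesis is that they respond through a regulatory region in common, looked at here by whether the rises were similar. The pair was chosen because both genes rose, so similar rises are no independent evidence. Their log2 fold changes differed by 0.18 ± 0.17 (SE), less than the 2 standard errors taken as the limit. That SE takes the 2 genes as independent, although both were read on the same 4 arrays. It therefore does not measure the spread of the difference, and the comparison cannot decide on the hypothesis. A change of the whole neighbourhood is argued against by the 19 other genes around them, with a median of 0.00325 and an upper quartile of 0.11. Whether the probe sets also bind transcripts of related ribonuclease genes could not be examined without probe sequences.

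The interferon-stimulated list had a median of 0.40, with 11 of 13 members positive and 5 passing over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.510), where no list passed, and with fry (adjusted p = 0.386). A larger share of immune cells in the GW4064 samples is argued against, since the upper quartiles of the T cell, B and plasma cell and myeloid lists were 0.04, -0.17 and 0.089, all under that median. A difference between single animals unrelated to the agonist cannot be told apart from an effect of GW4064 with 2 arrays per group.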
